A study of Homo sapiens with 6 samples.

How the data were processed

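RNA was sequenced from WPMY-1 cells, a human prostate stromal myofibroblast line immortalised with SV40 large T antigen. Per the labels, 3 libraries came from cells with a control vector (shvector) and 3 from cells with a short hairpin RNA against TRMT61A (sh61A). Per the labels' protocols, total RNA was extracted with Trizol, polyadenylated mRNA was captured on oligo(dT) beads and fragmented, cDNA was primed with random oligonucleotides, and size-selected fragments were amplified by PCR. No step of this protocol marks strand, and no unique molecular identifiers are named. The detection floors given here cover counting error only. Standard errors, p-values and standard deviations also take in the spread between libraries. Polyadenylated mRNA sequencing measures neither tRNA methylation nor translation.

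The authors deposited a table of read counts per gene, with whole numbers and no normalization. Per the submitters' processing notes the genome build was hg38. The aligner, the counting program, their versions, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Of the 62492 gene identifiers, 53015 carry a further number after the version, the form that GENCODE uses for releases mapped to the older GRCh37 build, so the build behind the counts is uncertain. No coordinates come from the deposited table. Positions printed here are those of GENCODE release 29 on GRCh38, matched by gene identifier without its version. Symbols came from the reference tables for 40928 identifiers, which held 99.7% of the counts. Of the 984 entries of the gene lists, 981 matched an identifier. Without stated strand use, reads from a gene and its antisense partner cannot be told apart, and genes with near-identical copies, such as ribosomal protein genes with their processed pseudogenes and the clustered histone genes, are uncertain where reads could be split between copies.

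Library totals ran from 43206338 to 50947091 counts, and expression is given in CPM, the count scaled to a common library total. A count of 3 equals 0.061 to 0.070 CPM. Genes were kept by the filterByExpr rule of edgeR 4.0.16 (R 4.3.3), which left 18105 genes holding 99.9% of the counts of each library. Libraries were scaled by the trimmed mean of M values (TMM), and CPM values use these scaled totals. The groups were compared with the robust quasi-likelihood test of edgeR over all 6 libraries with the group as the only term. A gene was called when its Benjamini-Hochberg adjusted p over all genes tested was under 0.05. All gene adjusted p-values in the report come from this test unless another tool is named. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Spreads of CPM are standard deviations over 3 libraries.

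Before the data were examined, 31 gene lists were fixed from textbook knowledge, among them markers of epithelial, immune and endothelial cells. The lists with at least 5 tested genes, 30 in all, were tested against the other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. The list p-values were adjusted with the Benjamini-Hochberg method over the 30 lists. Beside it stand camera with an estimated correlation and fry, which asks whether the genes of a list move, on balance, in 1 direction without reference to other genes. A further 5 lists were added after the data were seen. They were selenoproteins, 4 selenoprotein mRNAs described as sensitive to failed selenocysteine insertion together with GPX4, FOXO targets, snoRNA host genes and replication-dependent histones. Their p-values were adjusted over these 5 alone.

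The rule for the genes named in the report was set before the data were examined. It takes TRMT61A and its partner TRMT6. It takes the 10 highest and the 10 lowest log2 fold changes among called genes with a mean of at least 5 CPM, no overlap between groups and a gene symbol. From both TGF-beta lists, the collagen list and the contractile list it takes the 4 members with the smallest p. From every other list that was called, or of which at least 20% of tested members were called, it takes the 4 members with the smallest p in the direction of the list. From each list of another cell type it adds the 2 members with the highest mean CPM. A few genes that this rule takes are not reported here.

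On simulated counts with the means, dispersions and library sizes of the 18105 tested genes, the edgeR test recovered 64.2% of planted 1.25-fold changes, 82.1% of 1.5-fold changes and 93.9% of 2-fold changes, with 7 false calls among 167. The list test called a planted list of 30 genes shifted by 1.5-fold and none of 30 random lists, that is 0 of 30. Simulated genes were drawn independently of each other, so this does not measure false list calls among correlated genes. In the real lists the estimated correlation reached 0.749, for ribosomal proteins.

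Alternatives fixed before the data were examined were other scalings (the size factors of DESeq2, upper-quartile factors, library size only), other expression filters, DESeq2 1.42.0 and limma-voom as tests, a replicate block, leaving out each library in turn, fold limits and a stricter threshold, and other list tests. Added after the data were seen were removal of each library's trend with GC content and exonic length (natural splines, 5 degrees of freedom each), binomial thinning of every library to the smallest total, and leaving out genes with certain words in their 3' untranslated region (3' UTR). For the last, the log2 fold changes of 13449 genes with an annotated 3' UTR of at least 30 bases in GENCODE 29 were corrected for the trend with 3' UTR length and base composition. The mean of genes with each 7-base word was then compared with that of the others as a z value, for words in at least 20 genes. On shuffled fold changes with a planted word, the planted word ranked 1. These scans used Python 3.11.15 with numpy 2.4.6.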

Results

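The series title places this experiment within a study of N1-methyladenosine (m1A) in tRNA, benign prostatic hyperplasia and translational control of the TGF-beta pathway. TRMT61A is the catalytic subunit of the enzyme that, with TRMT6, methylates adenosine 58 of cytosolic tRNAs. Gene expression was measured by mRNA sequencing in 6 libraries of the stromal line WPMY-1, 3 with a control vector (shvector) and 3 with a hairpin against TRMT61A (sh61A). Total counts were 45975208, 44654963 and 43206338 in shvector and 50947091, 45456559 and 49671557 in sh61A. The comparison asks which mRNAs changed in level when TRMT61A was knocked down.

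TRMT61A mRNA was lower in all 3 sh61A libraries. The gene (ENSG00000166166.13_4) lies on the plus strand of chromosome 14 from 103529184 to 103537073 in GENCODE 29 on GRCh38. Its counts were 936, 953 and 889 in shvector and 352, 288 and 345 in sh61A, or 19.7 ± 0.556 CPM against 7.12 ± 0.382 CPM (SD, n = 3 each). This was a 2.76-fold decrease, with a log2 fold change of -1.46 (SE 0.0931, edgeR adjusted p = 1.65e-15). TRMT6, the partner subunit encoded on chromosome 20 from 5937235 to 5950558, rose 1.43-fold from 59.2 ± 1.49 to 84.8 ± 1.24 CPM (edgeR adjusted p = 9.94e-12).

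The change reached most expressed genes. Of the 18105 genes tested, 11558 (63.8%) were called, 5827 higher and 5731 lower in sh61A. The larger changes leaned downward: 2257 genes fell and 1156 rose by at least 2-fold, and 700 fell and 174 rose by at least 4-fold. The 3 libraries of each group did not overlap in CPM for 67.5% of tested genes, where chance gives 10%. Among 13634 protein-coding genes, 5285 rose and 4754 fell. Among 2293 lincRNA and antisense genes, 268 rose and 526 fell. Fewer genes had any count in sh61A (24758 ± 263) than in shvector (26398 ± 260), and mitochondrial transcripts took 5.43 ± 0.0478% against 5.79 ± 0.105% of counts. The balance of directions depends on the scaling. TMM factors were 0.939 to 0.951 in sh61A and 1.05 to 1.07 in shvector, so that scaling by library size only gives 4364 genes higher and 7247 lower and moves the median log2 fold change by -0.16. Upper-quartile scaling gives 4856 higher and 6652 lower, with a shift of -0.10.

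The libraries separated by group on the first principal component, which held 73.0% of the variance. Pearson correlations of log2 CPM were 0.988 to 0.990 within groups and 0.957 to 0.959 between them. Counts of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 3.92 to 8.17. The labels do not say whether the 3 libraries of a group came from separate cultures, and both groups are described as established lines, so p-values measure only the spread between these libraries, which may be technical.

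**Figure D1:**
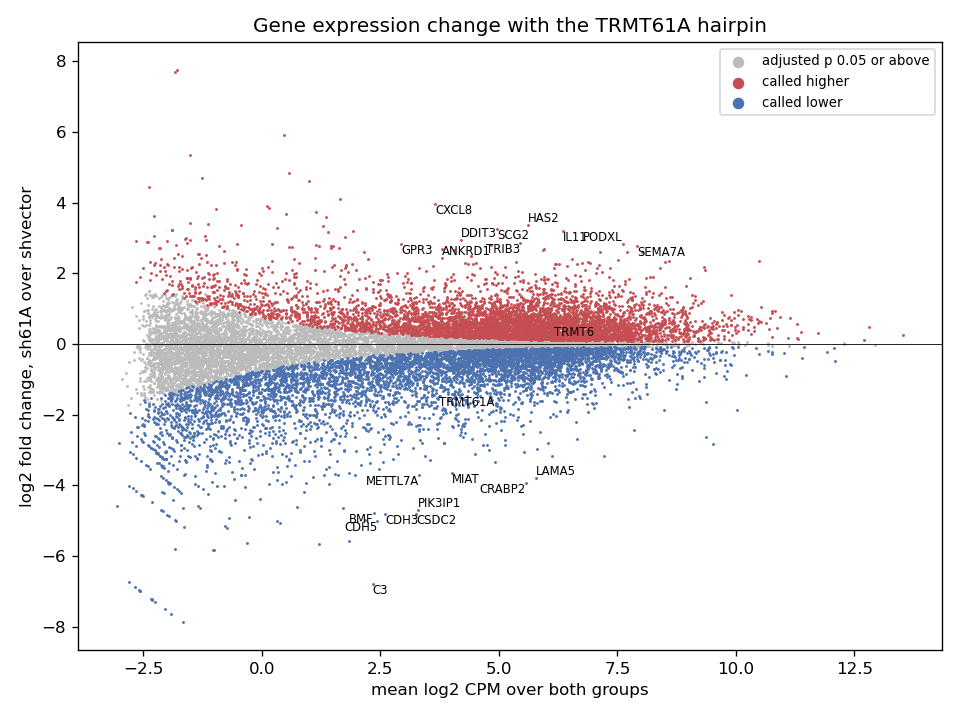
Each point is 1 of the 18105 tested genes, with its mean log2 CPM over both groups on the horizontal axis and its log2 fold change in sh61A over shvector on the vertical axis. Colour marks the 5827 genes called higher and the 5731 called lower, and labels mark TRMT61A, TRMT6 and the 10 most raised and 10 most lowered genes named by rule. Points at the lower left with fewer than 1 CPM include genes with no count in a library, where the fitted value depends on the prior count.

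Among the most raised genes, the chemokine gene CXCL8 rose from 1.51 ± 0.686 to 23.6 ± 3.36 CPM (log2 fold change 3.95, SE 0.246, edgeR adjusted p = 6.98e-07). HAS2, a hyaluronan synthase, rose by 3.38 on the log2 scale, SCG2, the precursor of secretoneurin, by 3.25, and IL11, a fibroblast cytokine, by 3.19, from 16.1 ± 0.752 to 148 ± 11.4 CPM. DDIT3 and TRIB3, both induced by the transcription factor ATF4, rose by 2.95 and 2.87. The others were PODXL (2.84), a sialomucin, GPR3 (2.83), a receptor that raises cyclic AMP, ANKRD1 (2.81), a target of the coactivator YAP, and SEMA7A (2.78), a membrane-anchored semaphorin that reached 421 ± 18.03 CPM.

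Among called genes that met the naming rule (mean of at least 5 CPM, no overlap, a symbol), the most lowered was C3, the central complement component. It went from 10.01 ± 0.611 to 0.0877 ± 0.0764 CPM (log2 fold change -6.80, SE 0.281, edgeR adjusted p = 7.04e-20). Its counts in the sh61A libraries were 6, 6 and 0, so the size of its decline is uncertain. With single libraries left out, its log2 fold change ran from -7.25 (without sh61A replicate 2) to -6.23 (without sh61A replicate 3). The cadherin genes CDH5 (-5.03) and CDH3 (-4.81) fell, as did CSDC2 (-4.82), the pro-apoptotic BMF (-4.79) and PIK3IP1 (-4.72), an inhibitor of phosphoinositide 3-kinase. CRABP2, which binds retinoic acid, fell from 88.7 ± 4.08 to 5.84 ± 0.573 CPM, and the laminin gene LAMA5 from 103 ± 5.16 to 7.39 ± 1.03 CPM. METTL7A (-3.70) and the long noncoding RNA MIAT (-3.65) completed the group.

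Genes of the TGF-beta pathway changed in both directions. Of 28 tested ligands, receptors and SMADs, 12 rose, 13 fell and 3 were not called. INHBA, which encodes the activin A subunit, rose 6.41-fold from 16.7 ± 0.81 to 107 ± 1.60 CPM. LTBP1, which tethers latent TGF-beta to the matrix, rose 4.65-fold, the activin antagonist FST 3.62-fold and the SMAD corepressor SKI 2.32-fold. Among those that fell, and chosen after their values were seen, were SMAD3 (log2 fold change -0.84), SMAD4 (-1.10) and SMAD6 (-1.56). The list was not called (camera adjusted p = 0.883). Its median log2 fold change was -0.08, while its mean lay 0.07 above that of the other genes.

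Of 31 tested TGF-beta target genes, 15 rose, 10 fell and 6 were not called, with a median log2 fold change of 0.17. Under library size only 14 were higher and 12 lower (median 0.01), and under upper-quartile scaling 14 and 11 (median 0.07). IL11 rose 9.16-fold and SPHK1, a sphingosine kinase, 3.39-fold. COL1A1, encoding the alpha-1 chain of type I collagen, fell 3.67-fold from 1635 ± 48.8 to 446 ± 8.73 CPM. The list was not called (camera adjusted p = 0.23; adjusted p = 0.724 with an estimated correlation). Without an expression filter the list was called (camera adjusted p = 0.0372). The same held when genes with at least 1 of 2 words in the 3' UTR, described at the end, were left out (camera adjusted p = 0.0405). Over the alternatives other than fry, its adjusted p ranged from 0.0372 to 0.724. Removing the filter also raised the mean difference from other genes in lists that stayed uncalled. It went from -0.033 to 0.18 for collagens and from -0.0094 to 0.20 for contractile genes. The proliferation, NRF2 and stromal growth factor lists, given below, gained a call in this setting too. The call without a filter is therefore not particular to TGF-beta targets. The 2 words were chosen as the most negative on these same fold changes. Leaving out the genes that hold them thus removes mainly genes that fell, COL1A1 among them. The call in that setting therefore decides nothing about TGF-beta targets.

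Matrix genes were likewise divided. Of 40 tested collagen and fibrillar matrix genes, 15 rose and 20 fell (camera adjusted p = 0.694). Under library size only 11 were higher and 22 lower, and under upper-quartile scaling 11 and 21. COL6A3 rose 5.14-fold from 468 ± 7.32 to 2405 ± 39.5 CPM, the basement membrane genes COL4A1 and LAMA4 rose 4.47-fold and 3.48-fold, and COL1A1 fell. Of 26 tested genes for crosslinking and remodelling of matrix, 12 rose and 13 fell (camera adjusted p = 0.601). Under library size only, and also under upper-quartile scaling, 9 were higher and 13 lower. ADAMTS1, MMP14 and TGM2, chosen after their values were seen, rose by 2.04, 1.34 and 1.88 on the log2 scale. Among those that fell were the metalloproteinase inhibitor TIMP3 (log2 fold change -1.14), the tissue plasminogen activator PLAT (-0.999) and the lysyl oxidases LOXL1 (-1.37) and LOX (-0.98). The mean of this list was 0.04 and its median -0.07.

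Contractile genes of myofibroblasts moved in both directions and were not called as a list. Of 27 tested, 10 rose, 10 fell and 7 were not called (camera adjusted p = 0.952, median 0.01, mean -0.14), while under library size only 8 were higher and 15 lower and under upper-quartile scaling 9 and 12. The tropomyosin gene TPM4 rose 3.14-fold from 240 ± 1.77 to 753 ± 13.7 CPM. MYH10, a nonmuscle myosin heavy chain, fell by 1.16 on the log2 scale, the leiomodin gene LMOD1 by 3.67 and the vinculin gene VCL by 0.54. Of 17 tested regulators of epithelial-mesenchymal transition, 7 rose and 6 fell (camera adjusted p = 0.86, median 0.09, mean -0.11). VIM, ITGB5, SNAI2 and CDH2 rose by 1.17, 0.76, 0.77 and 0.26. S100A4 (log2 fold change -2.48), CDH11 (-1.35) and SNAI1 (-1.08), chosen after their values were seen, fell, the last 2 from levels under 2 CPM. The call on SNAI1 was lost without shvector replicate 2 (-0.94), shvector replicate 3 (-0.95) or sh61A replicate 1 (-0.87). With scaling by library size only, 6 members of this list were higher and 8 lower.

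Genes of the integrated stress response rose together. Of 31 tested targets of ATF4, 27 rose and 2 fell, with a median log2 fold change of 1.10 (camera adjusted p = 8.82e-09; adjusted p = 0.268 with an estimated correlation). PSAT1, of serine synthesis, rose 3.69-fold from 129 ± 2.68 to 476 ± 12.6 CPM. PPP1R15A, a phosphatase subunit that reverses phosphorylation of eIF2 alpha, rose 4.26-fold. The amino acid transporter genes SLC7A1 and SLC3A2 rose 3.14-fold and 2.86-fold. Of 28 endoplasmic reticulum chaperone genes, 23 rose and 3 fell, with a median of 0.57 (camera adjusted p = 5.13e-06; adjusted p = 0.268 with an estimated correlation). HYOU1, HSPA5, CANX and HSP90B1 rose 2.15-fold, 1.94-fold, 1.91-fold and 1.75-fold.

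Genes of the translation machinery rose as well. Of 23 cytosolic aminoacyl-tRNA synthetases, 21 rose and 0 fell, with a median of 0.83 (camera adjusted p = 6.81e-09; adjusted p = 0.268 with an estimated correlation). AARS1 rose 3.72-fold from 123 ± 5.19 to 457 ± 16.1 CPM, and IARS1, GARS1 and NARS1 rose 2.22-fold, 2.17-fold and 2.05-fold. Of 77 cytosolic ribosomal proteins, 68 rose and 3 fell, with a median of 0.43 (camera adjusted p = 9.03e-11; adjusted p = 0.58 with an estimated correlation). RPL11 rose 2.58-fold, RPL6 1.69-fold, RPL23A 1.83-fold and RPS2 1.67-fold. Of 42 translation factors, 33 rose and 5 fell, with a median of 0.50 (camera adjusted p = 1.1e-06; adjusted p = 0.289 with an estimated correlation). EIF3F, EIF3B, EIF4G1 and EEF2 rose 2.75-fold, 2.24-fold, 1.89-fold and 1.82-fold.

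Of 31 genes of ribosome biogenesis, 29 rose and 0 fell, with a median of 0.71 (camera adjusted p = 1.91e-09; adjusted p = 0.289 with an estimated correlation). The nucleolar protein gene NOLC1 rose 6.03-fold from 73.6 ± 0.875 to 444 ± 7.03 CPM, TCOF1 2.64-fold, NPM1 1.90-fold and MYC, a transcription factor that drives ribosome synthesis, 2.502-fold. Of 48 tRNA modification enzymes outside the m1A group, 30 rose and 6 fell, with a median of 0.37 (camera adjusted p = 4.72e-04; adjusted p = 0.268 with an estimated correlation). The dihydrouridine synthase gene DUS1L rose 2.52-fold, the cytosine methyltransferase NSUN2 1.78-fold, the pseudouridine synthase PUS1 2.26-fold and the thiolation enzyme CTU1 4.03-fold. Of 12 enzymes and readers of m1A, 7 rose and 3 fell (camera adjusted p = 0.241). FTO rose by 0.64, YTHDF2 by 0.57 and TRMT10C by 0.42 on the log2 scale. With library size only, 5 of the 12 were higher and 5 lower.

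Immediate early genes were mostly higher: of 30 tested, 21 rose and 4 fell, with a median of 0.61 (camera adjusted p = 4.12e-04; adjusted p = 0.491 with an estimated correlation). FOSL1 rose 2.75-fold, DUSP5 2.81-fold and PHLDA1 2.17-fold. Of 23 targets of YAP and TEAD, 15 rose and 6 fell, with a median of 0.75 (camera adjusted p = 0.0149; adjusted p = 0.508 with an estimated correlation). DLC1, AMOTL1, ANKRD1 and LATS2 rose 3.06-fold, 2.499-fold, 6.99-fold and 2.89-fold. This call was lost when only genes with a mean of at least 5 CPM were tested (camera adjusted p = 0.0684), and over the alternatives other than fry the adjusted p ranged from 0.000197 to 0.508.

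Cholesterol genes and interferon-stimulated genes fell. Of 25 genes of cholesterol synthesis and uptake, 19 fell and 5 rose, with a median of -0.66 (camera adjusted p = 1.35e-04; adjusted p = 0.268 with an estimated correlation). LSS, SQLE and STARD4 fell 3.79-fold, 2.24-fold and 2.85-fold. Of 38 interferon-stimulated genes, 30 fell, 0 rose and 8 were not called, with a median of -0.88 (camera adjusted p = 4.11e-07; adjusted p = 0.268 with an estimated correlation). TRIM22 fell 4.04-fold from 27.5 ± 0.201 to 6.80 ± 0.673 CPM, IFIT3 2.13-fold, IRF1 2.64-fold and IFIT1 2.38-fold.

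In all, 11 of the 30 lists tested by camera were called, 9 up and 2 down. With an estimated correlation between genes 0 lists were called by camera, while 5 had an unadjusted p under 0.05 and fry called 26. Counts adjusted over the list alone were the same as those adjusted over all genes in 26 of 31 lists. They differed by 1 gene in the other 5, namely ribosomal proteins (69 higher), contractile genes (11 lower), regulators of epithelial-mesenchymal transition (7 lower), interferon-stimulated genes (31 lower) and stromal growth factors (11 lower).

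**Figure D2:**
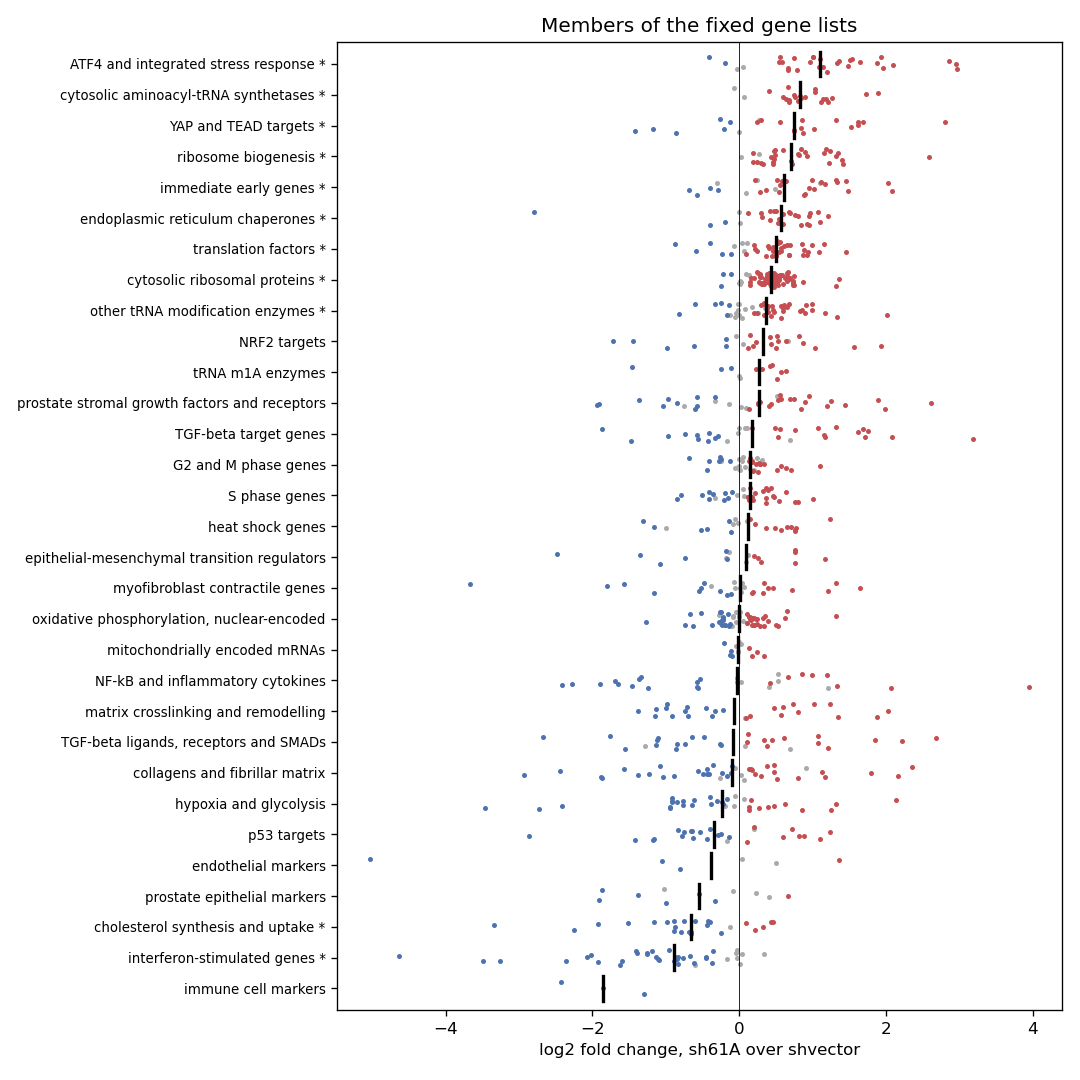
Points are tested members of the 31 fixed gene lists, placed by log2 fold change in sh61A over shvector. Red and blue mark genes called higher and lower, grey marks genes not called, black bars are list medians, and asterisks mark the 11 lists called by camera with its preset correlation; vertical scatter within a list carries no meaning. Medians run from -1.85 for immune cell markers to 1.10 for targets of ATF4.

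Proliferation genes rose more often than they fell, and neither list was called. Of 34 S phase genes, 20 rose and 10 fell (camera adjusted p = 0.145), with RFC2, CDT1, RRM1 and E2F1 higher by 0.76, 0.81, 0.47 and 0.64 on the log2 scale. Of 37 genes of G2 and M phase, 16 rose and 7 fell (camera adjusted p = 0.145), with BIRC5, TPX2, CDC25B and AURKB higher by 1.10, 0.52, 0.57 and 0.70. Under library size only the counts became 13 higher and 14 lower for S phase, and 10 higher and 15 lower for G2 and M. Without an expression filter both lists were called higher (camera adjusted p = 0.0299 each), and the G2 and M list also after removal of the GC and length trend (camera adjusted p = 0.0445). Removing the filter raised the mean difference of uncalled lists as well, as given with the TGF-beta targets. With the filter and an estimated correlation the adjusted p was 0.639 for S phase and 0.442 for G2 and M. Of 26 p53 targets, 8 rose and 16 fell (camera adjusted p = 0.145). TP53INP1 fell from 61.5 ± 1.78 to 8.46 ± 0.586 CPM, and the cell cycle inhibitor CDKN1A, the death receptor FAS and the repair gene DDB2 fell 2.23-fold, 2.68-fold and 2.25-fold. WPMY-1 carries SV40 large T antigen, which binds p53.

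Metabolic genes were divided. Of 34 genes of hypoxia and glycolysis, 19 fell and 11 rose (camera adjusted p = 0.145). LDHA fell from 2771 ± 65.4 to 1476 ± 40.5 CPM, and TPI1, ALDOC and BNIP3L fell 1.88-fold, 5.32-fold and 1.70-fold. Of 56 nuclear genes of oxidative phosphorylation, 24 rose and 19 fell (camera adjusted p = 0.86). UQCRC2, ATP5PB and SDHB rose 1.57-fold, 1.44-fold and 1.55-fold. The majority of this list turned under library size only, with 10 higher and 29 lower, and under upper-quartile scaling, with 13 higher and 24 lower. Of 13 mitochondrially encoded mRNAs, 4 rose and 4 fell (camera adjusted p = 0.883, median -0.01, mean 0.03). MT-ND2, MT-CO1, MT-ND1 and MT-CYB were higher by 0.34, 0.25, 0.18 and 0.14. Under library size only the counts were 2 higher and 9 lower, MT-ND1 stood at 0.02 and was not called, and MT-CYB stood at -0.02. MT-CYB was also not called under upper-quartile scaling (0.04) or when only genes with a mean of at least 5 CPM were tested (0.04).

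Of 28 NF-kB and inflammatory genes, 8 rose and 13 fell (camera adjusted p = 0.6). CXCL8 rose, while TNFAIP2, CCL2, BIRC3 and NFKB2 fell 2.57-fold, 4.86-fold, 5.35-fold and 2.36-fold. Of 22 heat shock genes, 11 rose and 6 fell (camera adjusted p = 0.241), with HSPD1, HSP90AA1, HSPA8 and HSP90AB1 up 2.35-fold, 1.69-fold, 1.72-fold and 1.64-fold. Under library size only 9 heat shock genes were higher and 9 lower. Of 24 targets of NRF2, 15 rose and 6 fell (camera adjusted p = 0.0758), including the cystine transporter SLC7A11 (3.81-fold), SQSTM1 (1.82-fold), GCLM (1.77-fold) and MAFG (1.55-fold). The NRF2 list was called without an expression filter (camera adjusted p = 0.00431), without sh61A replicate 1 (0.0347) and without sh61A replicate 2 (0.049), and with all libraries, the filter and an estimated correlation its adjusted p was 0.639. Of 36 stromal growth factors and receptors, 20 rose and 10 fell (camera adjusted p = 0.0832). GREM1, an antagonist of bone morphogenetic proteins, rose 6.10-fold from 39.5 ± 0.444 to 241 ± 10.1 CPM, DKK1 2.39-fold, IGFBP4 2.71-fold and FGF5 3.95-fold. This list too was called without an expression filter (camera adjusted p = 0.0244; adjusted p = 0.366 with the filter and an estimated correlation).

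Of 11 tested prostate epithelial markers, 1 rose and 6 fell (camera adjusted p = 0.201). KRT18 stood at 107 ± 3.44 and 102 ± 2.98 CPM, and KRT8 fell from 48.2 ± 0.936 to 33.1 ± 0.743 CPM. The call on KRT18 changed with the processing: it was not called (adjusted p = 0.116, edgeR), called lower with library size only (-0.24), upper-quartile scaling (-0.18), a mean of at least 5 CPM (-0.17) or without sh61A replicate 3 (-0.10), and called higher after removal of the GC and length trend (0.09). ACP3, KRT15 and CLDN4 fell from levels under 3 CPM, by 1.86, 1.90 and 1.37 on the log2 scale. Of the immune markers 3 were tested and all 3 fell. CD14 fell from 7.78 ± 0.824 to 1.44 ± 0.282 CPM and CD4 from 2.56 ± 0.144 to 0.71 ± 0.253 CPM. CSF1R stood at 0.554 ± 0.194 and 0.225 ± 0.111 CPM, and its call was lost in DESeq2, without a filter, after removal of the GC and length trend and without each of shvector replicates 1 and 2 and sh61A replicates 1 and 2 (log2 fold changes -1.09, -1.18, -0.99 and -1.24). Of 6 endothelial markers, 1 rose and 3 fell (camera adjusted p = 0.452). EGFL7 fell from 11.2 ± 0.704 to 5.43 ± 0.455 CPM and CDH5 from 10.5 ± 0.29 to 0.32 ± 0.0693 CPM. ESAM stood at 1.61 ± 0.421 and 0.923 ± 0.261 CPM, and its call was lost in DESeq2, after removal of the GC and length trend and without shvector replicate 1 (-0.79), shvector replicate 2 (-0.61) or sh61A replicate 1 (-0.61).

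**Figure D3:**
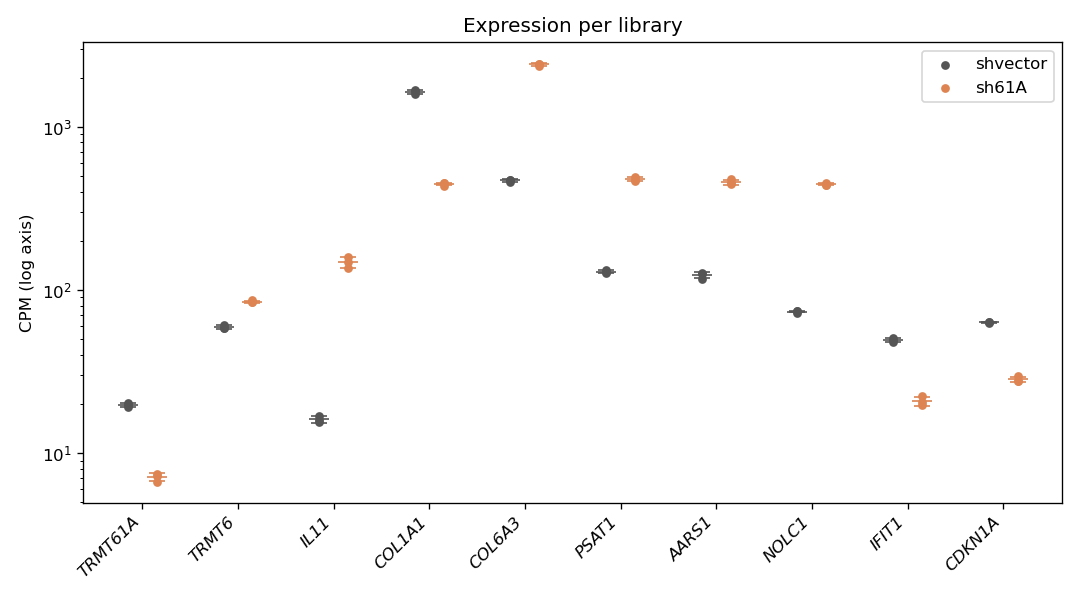
CPM on a log axis for 10 genes in the 3 shvector libraries (grey) and the 3 sh61A libraries (orange). Points are libraries, horizontal ticks are means and bars with caps are 1 SD. TRMT61A, COL1A1, IFIT1 and CDKN1A were lower in every sh61A library than in any shvector library, and the other genes were higher.

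Some of the named genes share a short sequence in the 3' UTR that went with lower expression across the transcriptome. Genes with the word ACAGACA in the 3' UTR (2017 genes) lay lower by a mean of -0.31 on the log2 scale after correction for 3' UTR length and base composition, and genes with CAGACAA (1491 genes) by -0.31. Of 133 genes named by rule with a searched 3' UTR, 18 held at least 1 of these words. This is a smaller share than the 20.3% of all 13449 genes searched, so the words were not enriched among named genes of both directions pooled. The pooled share cannot show whether they were enriched among the named genes that fell, since it also counts those that rose. Of the 18 genes with a word, the 11 with lower expression were COL1A1, TIMP3, LOX, MYH10, LMOD1, CDH5, TP53INP1, DDB2, LSS, IRF1 and BNIP3L. The 7 with higher expression were ITGB5, EIF3F, SLC7A11, MAFG, AMOTL1, GREM1 and FGF5. Of the 9 genes named above outside the rule, SMAD3, SMAD4, SMAD6 and CDH11 held at least 1 of the words, and the other 5 held neither.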

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

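The GC, thinning and 3' UTR word settings, and 30 of the named genes, were chosen after the data were seen, and the rest before. TRMT61A was lower and called in every setting it was run in, from -1.49 to -1.41 when single libraries were left out. In those fits 10893 to 11335 genes were called (5575 to 5657 higher, 5318 to 5678 lower), and 11 to 12 lists. Fold limits moved the count of called genes: 3413 (1156 higher, 2257 lower) at 2-fold and 6316 (2721 higher, 3595 lower) at 1.5-fold. Camera with an estimated correlation called 0 lists and fry 26. Both TGF-beta lists were called by fry, which tests a list against no change and not against other genes, so the calls do not rest on their mean differences from other genes (0.069 for ligands, receptors and SMADs, 0.53 for targets); for the first fry gave the direction as up, although its mean log2 fold change was -0.06. The targets list was called without an expression filter (0.71) and with word-bearing genes left out (0.75). The latter removes mainly genes that fell, since the words were chosen on these same fold changes. Named genes other than TRMT61A gave 2676 values under the alternatives, of which 2650 kept direction and side of the threshold, 20 lost and 4 gained a call and 2 reversed. The other lists gave 502, of which 447 kept both, 12 lost and 20 gained a call and 23 reversed. Depth limits the genes near 0.07 CPM, such as C3 in sh61A.

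The reversed list values are mean differences from other genes, none of a called list. Without a filter they were 0.18 for collagens, 0.20 for contractile genes and 0.021 for hypoxia. With a mean of at least 5 CPM they were -0.13 for matrix remodelling, -0.0093 for epithelial-mesenchymal regulators, -0.0090 for oxidative phosphorylation, -0.021 for mitochondrial mRNAs and -0.35 for NF-kB. With word-bearing genes left out they were 0.14 for collagens, 0.18 for contractile genes, -0.078 for epithelial-mesenchymal regulators, -0.050 for NF-kB and 0.11 for endothelial markers, and after GC and length correction 0.022 for contractile genes. Leaving out single libraries gave -0.044 to 0.037 for collagens, -0.044 to 0.065 for contractile genes and -0.0081 to 0.081 for NF-kB. MT-CYB reversed under library size only (-0.018) and KRT18 after GC and length correction (0.093). The filters change which genes are tested and the word setting removes genes. Both also change the scaling, since TMM factors were computed from the genes kept. For the other changes the cause was not tested.

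A replicate block called 11642 genes (5886 higher, 5756 lower) and changed no call of the named genes and lists but that of CSF1R (-1.30). Deviations from the group means correlated by 0.151, -0.077 and 0.204 between libraries of the same number, and shvector 1 correlated best with sh61A 2, so the shared numbers are not treated as pairs.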

Other observations

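The lists described here with their genes, and all tests on the joined site, on the share of declines with a word and on GPX4 alone, were chosen after the data were seen, as were the correction for GC content and length, the thinning and the removal of word-bearing genes. The host genes of small nucleolar RNAs, whose introns carry RNAs that guide modification of ribosomal RNA, rose: of 20 tested, 18 were called higher and 1 lower, with a median log2 fold change of 0.79 (camera adjusted p = 5.04e-06 over the added lists; adjusted p = 0.123 with an estimated correlation). GAS5 rose by 1.17, SNHG8 by 1.49 and SNHG12 by 1.06, while SNHG14 fell by 0.63. Of 20 FOXO targets, 14 fell and 4 rose, with a median of -0.66 (camera adjusted p = 0.00327; adjusted p = 0.123 with an estimated correlation). SESN3 fell by 3.11, KLHL24 by 1.42, FBXO32 by 1.38 and GABARAPL1 by 1.08, while IRS2 rose by 1.18. The 3' UTRs of KLHL24 and FBXO32 hold at least 1 of the words described below. The list holds BMF, PIK3IP1 and TP53INP1, which were seen to fall before it was written, so it is not independent of them.

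Of 34 replication-dependent histone genes, 20 fell and 1 rose, with a median of -0.88 (camera adjusted p = 7.06e-04; adjusted p = 0.127 with an estimated correlation). H2BC21 fell by 1.91 and H3C10 by 1.63, and H2BC5 rose by 1.08. These mRNAs mostly lack a poly(A) tail, so poly(A) libraries record only part of them, and the clustered genes have near-identical copies. Under library size only and upper-quartile scaling the majority direction of these 3 lists stayed as given.

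The first pattern is the breadth of change, with 11558 of 18105 genes called. A trend with GC content and length as its whole cause is argued against, since 11761 genes were called after that trend was removed, and so is depth, since 11480 were called with all libraries thinned to the smallest total. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05: the real split called 11558 genes, and the highest of the other 9 called 0 with edgeR (85 to 149 at an unadjusted p under 0.05), 0 with DESeq2 and 0 with limma-voom. Each of these 9 mixes both groups, so the group difference adds to the spread within its sides and lowers its count. The contrast with the real split therefore decides nothing about chance. For lists, 3 of the 10 splits gave at least as many as the real 11, and each of the other 9, which still have an excess of 1 group on either side, called 6 to 11 lists by camera with its preset correlation. The knockdown, other effects of the hairpin and any difference between established lines that predates it stay open, since 1 hairpin label was compared with 1 control.

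The second pattern lies in the strong declines, the called genes at least 2-fold lower, and with all genes that hold the words named here left out, 9353 of 15378 genes were still called in either direction. Among 7-base words in the 3' UTRs of 13449 genes, ACAGACA had the most negative z (-13.9) and CAGACAA, shifted by 1 base, the next (-12.5), against 6.07 for the most positive word, and ACAGACA also occurs in coding exon 2 of TRMT61A (chromosome 14, 103530246 to 103530252, GENCODE 29 on GRCh38), while CAGACAA, and with it the joined site, does not occur in TRMT61A transcripts, so silencing of off-target mRNAs through a seed of the hairpin is a candidate explanation that, of these 2 words, the first alone ties to TRMT61A. The 556 genes with both words joined had a median of -0.38. It was -0.19 for the 2180 with 1 or both words but not the joined site, and 0.07 for the 10713 with neither. Joined minus unjoined was -0.196 (one-sided permutation p = 1e-05, the smallest that 100000 resamples can give). A small RNA acting through this site would give this order. However, both words were chosen as the most negative on these same fold changes, and genes with the joined site count toward both. The permutation also used fold changes without the 3' UTR correction, and median 3' UTR lengths differed (3431, 2855 and 1036 bases). The order is therefore not independent evidence for a small RNA. Direct silencing through these words in the 3' UTR as the whole cause of the strong declines is argued against, since 30.3% of them (489 of 1613) held a word. The share was 20.3% of all genes searched and 14.6% of genes at least 2-fold higher. These shares cannot show genes that fell as a consequence of a silenced mRNA, or through sites outside the 3' UTRs searched. Of the 9 most lowered named genes with a searched 3' UTR, 1 held a word. The hairpin sequence was not used here, and a 7-base match in a transcript is weak evidence by itself. A cellular small RNA with the same seed stays open. For the remaining declines the knockdown and indirect effects of the hairpin both stay open.

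The third pattern is GPX4, the selenoprotein that reduces lipid peroxides, which fell 8.997-fold from 125 ± 6.69 to 13.9 ± 0.512 CPM (log2 fold change -3.17, SE 0.0567, edgeR adjusted p = 2.6e-30). The hypothesis that mRNAs sensitive to failed selenocysteine insertion fell as a set stays open. It was tested on 4 mRNAs without GPX4. Of these, 2 were called lower, SELENOW (-0.55) and MSRB1 (-0.77), and 2 higher, GPX1 (0.40) and SELENOH (0.50, but not called under library size only, 0.34). Their median lay 0.068 below that of the other selenoproteins, which meets neither bound set beforehand. The 19 selenoproteins other than GPX4 had a median of -0.01, at the 27.8th percentile of lists matched on GC content, length and CPM. This lay inside the central 95% set beforehand as the mark of a shared class. It was judged after the value was seen to decide nothing, since members went both ways. Of all 20, 9 were called higher, 9 lower and 2 not called (camera adjusted p = 0.966). Under library size only 7 were higher and 10 lower, and under upper-quartile scaling 8 and 10. GPX1, SELENOW, SELENOH and MSRB1 together with GPX4 were not called as a list (camera adjusted p = 0.412). The 50 genes nearest to GPX4 in GC content, length and CPM had a median of 0.33, which argues against a class that fell with it. The lowest of them stood at -1.37, but GPX4 was chosen for its fall, so its place below them carries little weight. The 3' UTR of GPX4, 215 bases long, holds the joined site. It is itself the 1 of 1177 (0.085%) of that length or shorter that does, so there is no other to set it against. A part played by the site stays open, as does the knockdown. Among other genes with a word, chosen here for their size, ARL6IP5 and DPYSL3 with the joined site fell 9.003-fold and 6.24-fold. SCD and CDC42, with at least 1 word but not the joined site, fell 7.19-fold and 5.41-fold.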
